A study of Mus musculus with 3 samples.

How the data were processed

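Liver polyA RNA of 3 groups of male C57BL/6J mice was sequenced, 1 library per group: control (normal chow), NASH (western diet with liquid fructose) and TH-treated NASH (the same diet, with T3 and T4 in the fructose drinking water for the last 8 weeks). Per the labels' protocols, mRNA was enriched on oligo(dT) beads, fragmented, and copied with random hexamers. Per the submitters' processing notes, TopHat2 and HTSeq were used; their versions, settings and strand mode and the genome build are not given in the sources used here. The deposited values are FPKM per gene that the authors made, 1 column per library, beside gene length, position and type.

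The table listed 35275 genes, 22026 of them protein-coding and 7373 pseudogenes. Of the gene IDs, 34490 are also in GENCODE M21, 34486 of these on the same chromosome and 34447 overlapping, but only 24932 have the same start and end, so positions are printed as the deposited table gives them. As deposited, 27 symbols stood as dates, the form a spreadsheet gives such names, and gene IDs were used for these. Within a library, FPKM multiplied by gene length came in whole multiples of 1 smallest step, the worth of 1 fragment, which was estimated from the low values. Divided by that step, 100% of values above 0 were whole within 0.01 fragment. The library total that the step implies equalled the sum of these fragments: 54576236 in control, 47009255 in NASH and 38303410 in TH-treated NASH. The 10 most abundant genes took 16.9%, 17.1% and 14.9% of fragments and the mitochondrial genome 4.50%, 4.96% and 6.72%. A gene 2 kb long with no fragment could have stood at up to 0.0275, 0.0319 and 0.0392 FPKM, from 3 counts per library.

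Log2 ratios were taken as log2(FPKM + 1) of one library minus the other, a scale that understates the fold of low genes. Counts of genes and medians of all genes were taken over genes with at least 1 FPKM in either library of the pair. Gene lists instead kept the same members in every comparison, those with at least 1 FPKM in any of the 3 libraries. A list member can therefore lie below 1 FPKM in both libraries of a pair. Genes were counted as higher or lower from 2-fold on that scale. With 1 library per group there is no estimate of spread, so no test between groups was run and no p-value is given. Fold ratios of single genes are ratios of the FPKM values with an exact 95% interval (conditional binomial, Clopper-Pearson) from the fragments, and those of single libraries are exact Poisson intervals. PCR copies are not independent molecules, so intervals and floors hold for counting error only. For a gene with no fragment in one library the fold is a lower bound against 3 counts in that library.

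In advance, 40 gene lists were fixed: metabolic pathways, matrix and cell type markers, stress responses, sex-biased liver genes, and markers of blood and of neighbouring tissues. They hold 772 entries, of which 770 were found and 2 not. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, which describes these libraries and is no test between conditions; a list is called apart beyond percentiles 2.5 and 97.5. Setting genes with no fragment at their floor moved list medians by at most 0.0429. The genes to name were also chosen by a rule fixed beforehand: per comparison the 12 highest and 12 lowest log2 ratios among genes of at least 5 FPKM in either library with a regular symbol, up to 4 members per list with the largest ratios, the 12 genes furthest off and back, and Thra, Thrb, Dio1, Thrsp, Alb and Col1a1; the Y-linked genes, Xist and the blood and Cyp3a genes summed in the checks were added after seeing the data. Some list members that the rule names are not reported here.

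NASH was compared with control and TH-treated NASH with NASH, as the series names them, and TH-treated NASH with control besides. For genes off in the first and back in the second, 100 sets of 3 unchanged libraries were drawn at these depths. They give the correlation that counting noise in the shared NASH library brings, and they hold no difference between animals. Settings planned before the data were examined were pseudocounts of 0.1 and 5 FPKM, no filter or at least 5 FPKM, scaling to equal totals, median-of-ratios and TMM scaling, rescaling without the 50 most abundant genes, protein-coding genes only, thresholds of 1.5-fold and 4-fold, and random lists without matching. Thinning to equal depth, centring by gene length, requiring the counting interval to pass 2-fold, and leaving out blood, Mup and sex-biased genes were added after seeing the data.

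The steps were tested on simulated data for NASH against control over the 35275 genes. Of 50 genes set 3-fold higher, 50 passed 2-fold, and of 50 set 3-fold lower, 41 did, the number whose simulated mean lay past 2-fold on the log2(FPKM + 1) scale. Of 50 genes set 1.5-fold higher and 50 set 1.5-fold lower none passed, 3 of 11027 unchanged genes passed, and 10 of 200 random lists fell outside the central 95%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.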

Results

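Bulk liver RNA sequencing covered 3 libraries, 1 per group, from male C57BL/6J mice that were 10 weeks old when the diets began. The control library came from mice on normal chow, and the labels do not state their total weeks or their age at collection. The NASH library, named for nonalcoholic steatohepatitis, came from untreated mice on a western diet with liquid fructose, and its label names 24 weeks. No fructose percentage is recorded for this library. The TH-treated NASH library came from mice on the same diet for 16 weeks that then received the thyroid hormones T3 and T4 for 8 weeks in drinking water with 15% fructose, at doses the labels give as 35 and 7 ng/g. In the order control, NASH and TH-treated NASH, the libraries held 54576236, 47009255 and 38303410 fragments on genes, and 10598, 11324 and 11094 genes stood at 1 FPKM (fragments per kilobase of gene length, scaled to the total of the library) or more. A gene near 1 FPKM rested on a median of 180, 156 and 133 fragments. With 1 library per group, no difference has a replicate check, and the labels do not say whether a library pools animals. "NASH", "control" and "TH-treated NASH" below name these libraries. A fold is a ratio of FPKM values, and a range in brackets after it is its 95% counting interval, which covers counting error only and is given for the leading genes and for genes with few fragments. Members of a gene list count as higher or lower from 1.5-fold on the log2(FPKM + 1) scale. The percentile places the list's median log2 ratio among those of 10000 random lists matched on expression. List members are those at 1 FPKM or more in any of the 3 libraries. Some, such as Elane, Gzma, Cyp3a41a and Cyp3a44, reached 1 FPKM only in TH-treated NASH and lay below it in both NASH and control.

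The comparison of NASH with control asked how the liver transcripts of mice on the western diet with fructose differed from those of mice on chow. Cidea, a protein that enlarges lipid droplets, stood at 43.5 FPKM in NASH and 0.346 in control, 126-fold higher (82.8 to 200.97), and its relative Cidec was 11.6-fold higher (10.7 to 12.6). Gpnmb, a glycoprotein of lipid-laden macrophages, was 179-fold higher (82.0 to 490) on 6 control fragments, and Col1a1, a chain of type I collagen, was 5.21-fold higher (4.68 to 5.80). Enzymes of cholesterol synthesis were lower, among them Idi1 at 11.9-fold (10.7 to 13.3) and Sqle at 11.6-fold (10.4 to 12.9). Of 11499 genes at 1 FPKM or more in either library, 383 were at least 2-fold higher in NASH and 89 at least 2-fold lower on the log2(FPKM + 1) scale, so that 81.1% of these were higher. The median log2 ratio of all genes compared was 0.12 as deposited, 0.01 after median-of-ratios scaling and −0.05 after TMM (trimmed mean) scaling. Unless another setting is named, the ratios below are as deposited and not centred on that median. After TMM scaling 265 genes were higher and 137 lower (65.9% higher), and after centring by gene length 287 were higher and 128 lower (69.2% higher).

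Further genes with large differences in NASH were Ly6d, a surface antigen, 119-fold higher (76.9 to 195), Apoa4, an apolipoprotein, 18.9-fold higher at 2919 FPKM, and Cfd, the complement factor adipsin that fat tissue makes in quantity, 16.7-fold higher (14.0 to 20.1). On the lower side, Moxd1, a monooxygenase-like protein, stood at 0.441 against 18.9 FPKM, 42.9-fold lower (33.5 to 55.9). Enho, which encodes the secreted peptide adropin, was 29.9-fold lower (23.1 to 39.3), and Serpina1e, an alpha-1-antitrypsin gene that shares reads with its near-identical relatives, was 15.2-fold lower (15.1 to 15.4) at 431 FPKM. As the deposited table gives them, Cidea (ENSMUSG00000024526) lies on chromosome 18 from 67343564 to 67367794, Cidec (ENSMUSG00000030278) on chromosome 6 from 113424634 to 113435760 and Gpnmb (ENSMUSG00000029816) on chromosome 6 from 49036518 to 49058182. Col1a1 (ENSMUSG00000001506) lies on chromosome 11 from 94936224 to 94953042, Idi1 (ENSMUSG00000058258) on chromosome 13 from 8885501 to 8892451, Sqle (ENSMUSG00000022351) on chromosome 15 from 59315077 to 59331192 and Enho (ENSMUSG00000028445) on chromosome 4 from 41638144 to 41640324. The genome build of these positions is not given in the sources used here.

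**Figure D1:**
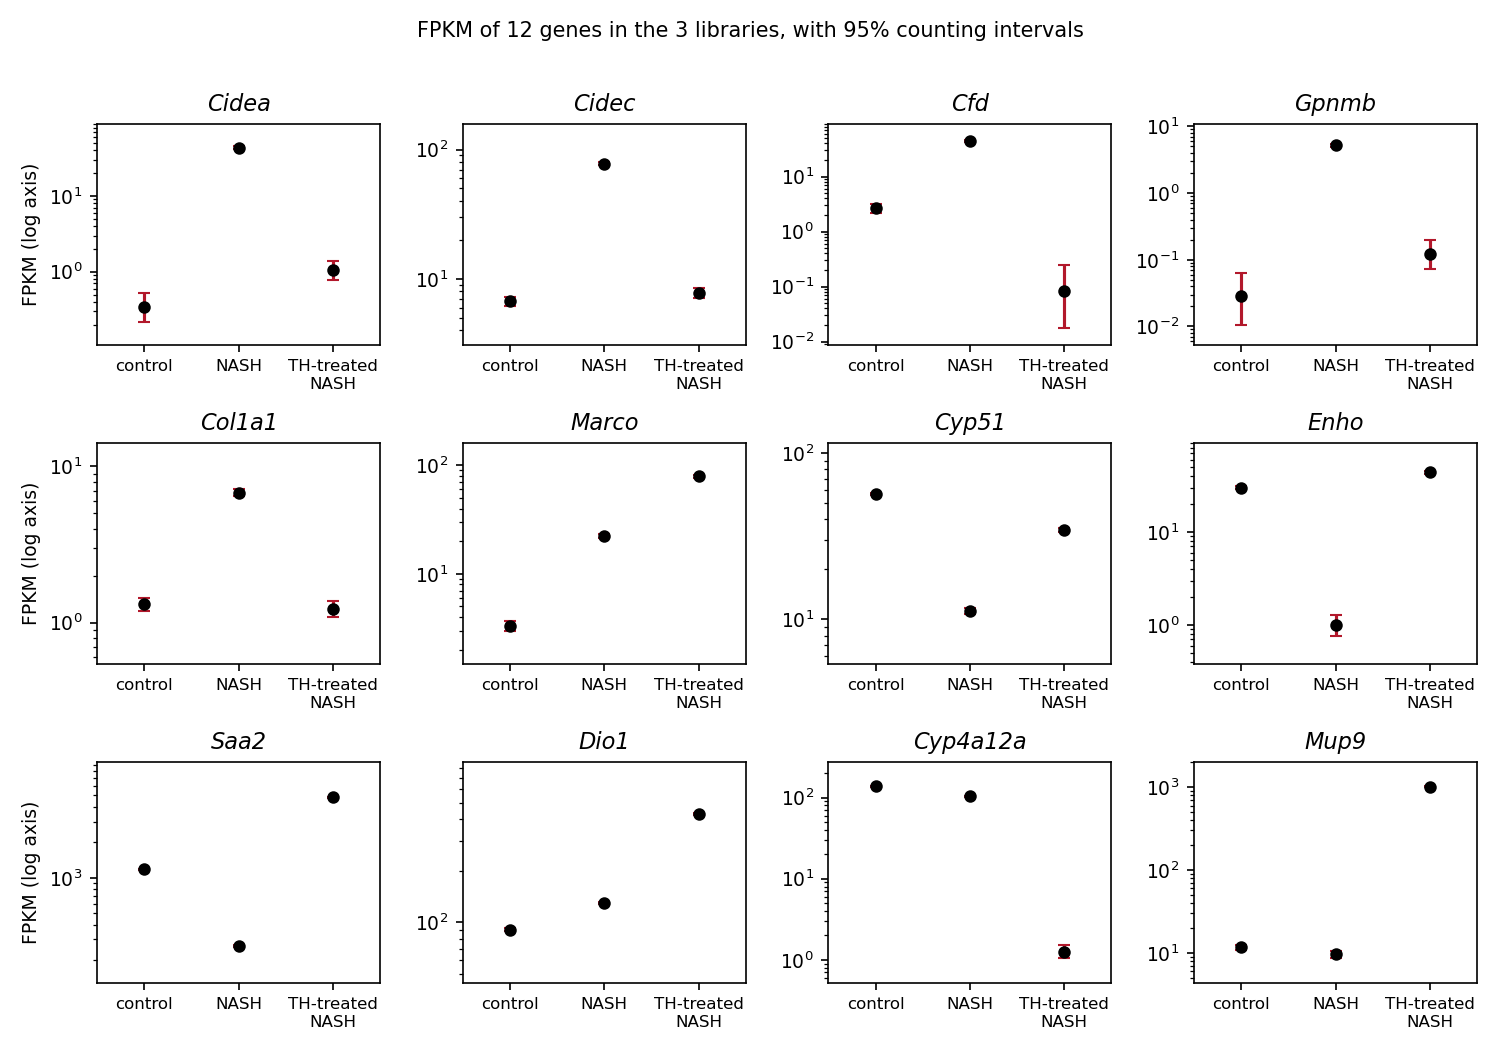
FPKM on a log axis of 12 genes in the control, NASH and TH-treated NASH libraries, 1 point per library with its 95% counting interval as the bar. Cidea stands at 0.346, 43.5 and 1.05 FPKM, Dio1 at 90.3, 129 and 429.7, and Cyp4a12a at 137, 104 and 1.26.

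In the list for lipid droplets and fatty acid uptake, 10 of 16 members were higher in NASH and 1 lower, with a median log2 ratio of 0.74 that lay above all random lists (percentile 100). Cd36, a fatty acid translocase, was 4.48-fold higher and Lpl, lipoprotein lipase, 5.37-fold higher, while Fabp5, a fatty acid binding protein, was 3.77-fold lower. For de novo lipogenesis 8 of 18 members were higher and none lower, with a median of 0.34 (percentile 100). Scd1, the stearoyl-CoA desaturase, stood at 6747 against 1786 FPKM, 3.78-fold higher, and the lipogenic transcription factor Srebf1 was 2.26-fold higher. Sphingolipid metabolism had 4 of 20 members higher, a median of 0.29 (percentile 98.9) and Smpd3, a sphingomyelinase, 10.1-fold higher (8.47 to 12.1). Triglyceride synthesis and export had 3 of 18 members higher and 1 lower with a median of 0.16 (percentile 91.3) that turned to −0.03 after TMM scaling. Its member Mogat1, a monoacylglycerol acyltransferase, was 11.9-fold higher (8.59 to 16.9), and the phosphatidate phosphatase gene Lpin1 was 1.60-fold lower.

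In the list for gluconeogenesis, glycolysis and fructose, 7 of 19 members were higher and 1 lower, with a median of 0.47 (percentile 100). The hexokinase gene Hk2 was 7.26-fold higher (5.40 to 9.92), whereas Pck1, a rate-controlling enzyme of gluconeogenesis, was 2.31-fold lower. Peroxisomal fatty acid oxidation had 2 of 18 members higher with a median of 0.28 (percentile 99.8), among them the thiolase Acaa1b at 1.71-fold. PPARA targets had 5 of 17 higher and 3 lower with a median of 0.26 (percentile 99.3), with the pantetheinase Vnn1 2.82-fold higher and the fatty acid hydroxylase Cyp4a14 2.08-fold lower. Ketogenesis had 1 of 6 higher, Bdh1 at 1.57-fold, with a median of 0.34 (percentile 98.0). The thyroid hormone response list had 4 of 20 higher and 1 lower with a median of 0.24 (percentile 98.7); its member Thrsp, a lipogenic regulator induced by thyroid hormone, was 2.04-fold higher. The receptors stood at 7.40 against 5.77 FPKM for Thra and 6.69 against 6.43 FPKM for Thrb.

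Mitochondrial fatty acid oxidation had 1 of 21 members higher, Acot2 at 2.85-fold, with a median of 0.13 (percentile 92.0) that turned negative under median-of-ratios scaling, TMM scaling and centring by gene length. None of the 38 nuclear genes of oxidative phosphorylation and none of the 12 mitochondrial genome transcripts was 1.5-fold off. The medians were 0.01 (percentile 57.8) and −0.01 (percentile 43.7), and their sign turned under 4 settings for the former and 2 for the latter. Against random lists not matched on expression the nuclear list lay at percentile 1.1. Mitochondrial biogenesis and uncoupling had 2 of 16 higher and 1 lower with a median of −0.06 (percentile 1.18), which was 0.14 among genes of at least 5 FPKM. Ucp2, an uncoupling protein, was 2.16-fold higher and the coactivator Ppargc1b 2.14-fold lower. Autophagy, mitophagy and lysosome genes had 3 of 27 higher and 1 lower with a median of 0.14 (percentile 89.3), negative after TMM scaling and centring by gene length. The lysosomal proteases Ctsd and Ctsb were 1.58-fold and 1.57-fold higher, and the autophagy kinase Ulk1 was 1.56-fold lower.

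Of 24 genes of cholesterol synthesis, 19 were lower in NASH and none higher, 16 of them at least 2-fold lower, and the median of −1.21 lay below all random lists (percentile 0). Cyp51, the lanosterol demethylase, stood at 11.3 against 57.0 FPKM, 5.04-fold lower, and Msmo1, the next oxidase of the pathway, was 4.93-fold lower. Bile acid synthesis and transport had 4 of 21 members higher and 1 lower, with a median of −0.12 (percentile 0.83). The members past 1.5-fold included the sterol exporters Abcg5 and Abcg8, 2.92-fold and 2.09-fold higher, and the hydroxylase Cyp7b1, 2.93-fold lower.

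Matrix and macrophage genes were mostly higher in NASH. Of 32 collagen and matrix genes, 23 were higher and none lower, with a median of 0.81 (percentile 100). The matrix metalloproteinase Mmp12 was 19.2-fold higher (14.3 to 26.3), Col1a2 4.34-fold and Col3a1 3.71-fold higher. Stellate cell markers had 8 of 16 higher and none lower, with a median of 0.63 (percentile 100), among them Dpt at 3.81-fold and Pdgfrb at 2.34-fold. Among monocyte and lipid-associated macrophage markers, 17 of 19 were higher and 1, Fabp5, lower, with a median of 1.82 (percentile 100). The tetraspanin Cd63 was 6.73-fold and the antigen-presentation gene H2-Aa 4.26-fold higher. Kupffer cell and macrophage markers had 15 of 17 higher and 1 lower with a median of 1.47 (percentile 100), with the scavenger receptor Marco 6.77-fold higher and Cd163 1.89-fold lower. Chemokines, cytokines and inflammasome genes had 17 of 23 higher and none lower with a median of 0.81 (percentile 100). Ccl2, which attracts monocytes, was 8.92-fold higher (5.86 to 14.1) and Ccl5 5.14-fold higher (3.78 to 7.12). Cholangiocyte and progenitor markers had 6 of 9 higher with a median of 0.62 (percentile 99.8), with Krt23 7.60-fold higher (5.85 to 10.002). Beside these groups, 2 of 9 neutrophil markers were higher, with a median of 0.26 (percentile 64.4). The log2(FPKM + 1) scale understates the fold of low genes. Summed over all 13 genes of that list, NASH held 2.34 times the control fragments per fragment sequenced (2.05 to 2.68). Among erythroid and blood markers 2 of 8 were higher, the platelet chemokines Pf4 at 6.17-fold (3.75 to 10.7) and Ppbp at 8.96-fold (5.11 to 16.9), with a list median of 0.39 (percentile 98.6), and summed haemoglobin stood at 347 against 255 FPKM.

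Hepatocyte markers had 6 of 21 lower in NASH and 1 higher with a median of −0.46 (percentile 0), with the fibrinogen chain Fgb 1.86-fold lower and glutamine synthetase, Glul, 1.99-fold higher. Alb, albumin, stood at 20265 against 32685 FPKM, 1.61-fold lower. Acute phase proteins had 10 of 19 lower and 3 higher with a median of −0.63 (percentile 0). Serum amyloid genes Saa2 and Saa1, which share reads, were 4.47-fold and 3.54-fold lower, while Orm3, an orosomucoid, was 14.4-fold higher (11.2 to 18.7) and Lcn2, lipocalin 2, 2.43-fold higher. Among male-biased liver genes 8 of 16 were lower and none higher, with a median of −0.62 (percentile 0), including Susd4 at 3.59-fold and Selenbp2 at 3.33-fold. Female-biased genes had 4 of 15 higher and 1 lower with a median of 0.17 (percentile 48.2), with Cyp2a4 17.995-fold higher (7.96 to 50.3) and Cyp2b9 77.8-fold higher (21.1 to 649) on 2 control fragments. Cyp2 genes share reads with close relatives. Xenobiotic metabolism had 2 of 19 higher and 2 lower with a median of −0.19 (percentile 0.155), with the carboxylesterase Ces2a 2.26-fold lower. NRF2 targets and other oxidative stress genes had 8 of 21 higher and 1 lower, with a median of 0.12 (percentile 81.2) that was negative under median-of-ratios scaling, TMM scaling and centring by gene length. Glutathione S-transferases lay on both sides, Gstm3 4.15-fold higher and Gsta1 4.13-fold higher (3.53 to 4.86) but Gstp1 3.01-fold lower.

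In this comparison the thyroid hormone response and ketogenesis lists returned inside the central 95% of random lists with a pseudocount of 5 FPKM and among genes of at least 5 FPKM, and sphingolipid metabolism among the latter. Against random lists not matched on expression, the thyroid hormone response, ketogenesis, PPARA target and peroxisomal oxidation lists lost their call, and the erythroid list lost it with a pseudocount of 0.1 FPKM and after scaling to equal totals.

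The comparison of TH-treated NASH with NASH asked how liver transcripts of mice given thyroid hormone on the diet differed from those of untreated mice on it. Dio1, the deiodinase that activates T4 and a classic thyroid hormone target, stood at 429.7 against 129 FPKM in NASH, 3.32-fold higher (3.25 to 3.40). The lipid droplet genes Cidea and Cidec were 41.3-fold lower (31.0 to 56.4) and 10.01-fold lower (9.15 to 10.98), and Col1a1 was 5.54-fold lower (4.88 to 6.30). Acute phase genes were higher, with Saa2 at 4817 against 263 FPKM, 18.3-fold (17.9 to 18.7). Liver genes that differ by sex in mice stood far apart: the male-biased hydroxylase Cyp4a12a was 82.2-fold lower (68.5 to 99.5), and the female-biased Cyp3a44, with no NASH fragment, was at least 2995-fold higher at 97.4 FPKM, taking 3 counts as the floor of a library at 0. Of 11734 genes at 1 FPKM or more in either library, 320 were at least 2-fold higher and 325 at least 2-fold lower on the log2(FPKM + 1) scale (49.6% higher). The median of all genes was −0.03 as deposited, −0.14 after scaling to equal totals and −0.13 after rescaling without the 50 most abundant genes. The splits were then 351 higher and 577 lower (37.8% higher) and 263 higher and 418 lower (38.6% higher).

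Among the genes furthest apart were Cfd, 521-fold lower (178 to 2527) on 3 fragments, Ddah1, which breaks down methylated arginines, 108-fold lower (84.4 to 141), the steroid dehydrogenase Hsd17b6, 80.6-fold lower (59.9 to 111), and the zinc importer Slc39a4, 33.4-fold lower (24.7 to 46.3). On the higher side stood Enho, 43.7-fold (33.8 to 57.5), Igfbp1, a secreted binding protein of insulin-like growth factors, 17.5-fold (16.5 to 18.7), Akr1c18, a steroid reductase with no NASH fragment, at least 395-fold, and the crystallin gene Crybb3, 108-fold (67.5 to 187). The major urinary protein genes Mup9 and Mup18 were 105-fold (95.4 to 116) and 79.7-fold higher (68.5 to 93.3), while Mup21 and Mup20 were 14.3-fold and 8.63-fold lower. Close copies among the Mup genes share reads, and the sum over all 51 Mup genes and pseudogenes was 22323 against 19359 FPKM. Dio1 (ENSMUSG00000034785) lies on chromosome 4 from 107291465 to 107307169, Cyp4a12a (ENSMUSG00000066071) on chromosome 4 from 115299046 to 115332815, Cyp3a44 (ENSMUSG00000054417) on chromosome 5 from 145773983 to 145805874, Saa2 (ENSMUSG00000057465) on chromosome 7 from 46751833 to 46754314 and Cfd (ENSMUSG00000061780) on chromosome 10 from 79890853 to 79892656.

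Sex-biased genes as a group stood apart on both lists. Female-biased genes had 10 of 15 higher and none lower with a median of 1.56 (percentile 100). Members that reached 1 FPKM only in TH-treated NASH, such as Cyp3a41a and Cyp3a44, are higher here by the entry rule. Cyp3a41a, with no NASH fragment, was at least 252-fold higher, Cyp2c69 was 48.7-fold higher (25.4 to 107) and the sulfotransferase gene Sult2a2 225-fold higher (39.8 to 8919) on 1 NASH fragment. Cyp3a16, Cyp3a41a, Cyp3a41b and Cyp3a44, close copies that share reads, together stood at 159 against 0.0123 FPKM, while the sum over all 9 Cyp3a genes was 622 against 1326 FPKM, 2.13-fold lower. Male-biased genes had 7 of 16 lower and 5 higher with a median of −0.41 (percentile 0.25). Cyp4a12b was 88.5-fold lower (64.4 to 125), and the sum over Cyp4a12a and Cyp4a12b, which share reads, was 83.8-fold lower, whereas Serpina1e was 6.11-fold higher. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together held 1.03 times the NASH fragments per fragment sequenced (0.997 to 1.07), chosen after these values were seen.

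Thyroid hormone response genes had 6 of 20 higher and 3 lower with a median of 0.29 (percentile 98.3). The hepatokine gene Fgf21 was 2.47-fold and G6pc, glucose-6-phosphatase, 2.25-fold higher, Thrsp stood at 485 against 389.7 FPKM, and the glycerol-phosphate acyltransferase Gpam was 2.996-fold lower. Thra was 1.81-fold and Thrb 1.44-fold lower. PPARA targets had 8 of 17 higher and 1 lower with a median of 0.49 (percentile 99.9), among them Cyp4a31 at 18.02-fold and Pdk4, an inhibitor of pyruvate oxidation, at 4.57-fold. Lipid droplet and uptake genes had 8 of 16 lower and 4 higher with a median of −0.52 (percentile 0); Pparg, a transcription factor of fat storage, was 5.72-fold lower (4.76 to 6.92), Cd36 2.51-fold lower and Fabp5 11.4-fold higher. De novo lipogenesis had 4 of 18 higher and 5 lower with a median of 0.07 (percentile 53.4), which was −0.04 after scaling to equal totals and without the 50 most abundant genes. Pyruvate kinase, Pklr, Srebf1 and Scd1 were 3.35-fold, 3.26-fold and 2.68-fold lower, and Pnpla3 was 4.64-fold higher. Triglyceride synthesis and export had 3 of 18 higher and 3 lower with a median of 0.28 (percentile 98.1), with Lpin1 6.37-fold and the lipase Pnpla2 2.52-fold higher and Mogat1 5.57-fold lower (4.24 to 7.43). Cholesterol synthesis had 14 of 24 higher and none lower with a median of 0.76 (percentile 100), led by Sqle at 3.96-fold, Idi1 at 3.69-fold and Mvd at 3.505-fold.

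Bile acid synthesis and transport had 1 of 21 higher and 4 lower with a median of −0.16 (percentile 4.99); the exporter Abcc3 was 13.5-fold lower (12.5 to 14.4) and Cyp7b1 3.21-fold higher. Gluconeogenesis, glycolysis and fructose genes had 6 of 19 lower and 4 higher with a median of −0.28 (percentile 0.975), with Pklr lower and Pdk4 higher as above. Sphingolipid metabolism had 2 of 20 lower with a median of −0.07 (percentile 38.7), Smpd3 at 4.48-fold and Sgms2 at 2.56-fold. Mitochondrial fatty acid oxidation had 3 of 21 lower and 1 higher with a median of −0.11 (percentile 8.57), with the dehydrogenase Acadm 1.95-fold lower and Etfb 1.71-fold higher. Peroxisomal oxidation had 7 of 18 lower and 4 higher with a median of −0.12 (percentile 9.26), with Abcd2 2.69-fold higher. Ketogenesis had 2 of 6 lower and 1 higher with a median of −0.46 (percentile 1.55), with Acat1 1.76-fold lower.

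Of 12 transcripts of the mitochondrial genome, 8 were higher and none lower, with a median of 0.68 (percentile 99.9). The cytochrome oxidase subunits mt-Co2 and mt-Co3 were 2.54-fold and 2.47-fold higher and mt-Cytb 1.40-fold higher, and mitochondrial transcripts took 6.72% of fragments against 4.96% in NASH. Nuclear genes of oxidative phosphorylation had 3 of 38 higher and 1 lower with a median of 0.17 (percentile 65.4, and 99.6 without expression matching), with Cox7a2 1.56-fold higher and Sdha 1.62-fold lower. Mitochondrial biogenesis and uncoupling had 1 of 16 higher, Gpd2 at 1.59-fold, with a median of 0.10 (percentile 89.7), and autophagy, mitophagy and lysosome genes had 1 of 27 higher, Ulk1 at 1.92-fold, and 3 lower with a median of −0.07 (percentile 16.7). Many genes of oxidative phosphorylation are short, and across 10902 protein-coding genes, which are not independent replicates, the log2 ratio had a rank correlation of −0.18 with gene length. The trend ran over all these genes, so it also bears on other lists of short or long genes, such as the collagens. In TH-treated NASH vs control it was −0.25 over 10671 genes.

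Matrix genes had 16 of 32 lower and 3 higher with a median of −0.59 (percentile 0); Mmp12 was 9.80-fold lower (7.62 to 12.8), Col3a1 3.77-fold and Col1a2 3.26-fold lower. Stellate cell markers had 2 of 16 lower and 1 higher with a median of −0.21 (percentile 5.47), with Pdgfrb 1.87-fold lower. Macrophage lists went apart. Monocyte and lipid-associated macrophage markers had 7 of 19 lower and 1 higher with a median of −0.49 (percentile 0.02), with Gpnmb 41.9-fold lower (26.4 to 71.0) and H2-Aa 2.72-fold lower. Kupffer cell and macrophage markers had 6 of 17 higher and none lower with a median of 0.49 (percentile 100), with Cd163 5.35-fold, Marco 3.55-fold, Timd4 2.56-fold and Clec4f 2.17-fold higher. Chemokines, cytokines and inflammasome genes had 5 of 23 lower and 3 higher with a median of −0.31 (percentile 0.18), with Ccl2 5.05-fold lower (3.44 to 7.63) and Cxcl14 14.2-fold higher (12.6 to 16.0). Cholangiocyte and progenitor markers had 4 of 9 lower with a median of −0.50 (percentile 0.34), with Krt23 27.1-fold lower (15.7 to 51.3). Acute phase proteins had 12 of 19 higher and none lower with a median of 0.81 (percentile 100), among them Orm2 at 13.1-fold, Saa1 at 10.2-fold and Lcn2 at 6.37-fold. Beside these groups, 8 of 9 neutrophil markers were higher with a median of 1.85 (percentile 100), with S100a8 11.9-fold higher (9.17 to 15.7) and Ngp 72.1-fold higher (27.8 to 267) on 4 NASH fragments. Members that reached 1 FPKM only in TH-treated NASH, such as Elane, are higher here by the entry rule, which lifts this median. Summed over all 13 genes of the list with no such rule, TH-treated NASH held 5.63 times the NASH fragments per fragment sequenced (5.17 to 6.13). Erythroid and blood markers had 6 of 8 higher and 1 lower with a median of 1.76 (percentile 100), and summed haemoglobin, whose genes share reads, stood at 1735 against 347 FPKM.

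Hepatocyte markers had 6 of 21 higher and 4 lower with a median of 0.30 (percentile 84.7, and 99.9 without expression matching); tyrosine aminotransferase, Tat, was 3.39-fold higher, Cyp1a2 2.33-fold lower and Alb 1.36-fold lower. Of 21 NRF2 targets and oxidative stress genes, 14 were lower and none higher, with a median of −0.78 (percentile 0). The glutathione S-transferases Gsta1, Gsta2 and Gstm1 were 52.2-fold (29.0 to 105), 15.3-fold (11.2 to 21.2) and 5.62-fold lower. Xenobiotic metabolism had 12 of 19 lower and 2 higher with a median of −0.76 (percentile 0), with Cyp2c29 5.10-fold, Cyp3a11 4.08-fold and the bilirubin-conjugating Ugt1a1 2.998-fold lower and the sulfotransferase Sult5a1 8.31-fold higher. These families share reads between close copies.

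The thyroid hormone response list returned inside the central 95% of random lists with a pseudocount of 5 FPKM and among genes of at least 5 FPKM, as did triglyceride synthesis under both and with no filter on low values. So did cholangiocyte markers with no filter and at 5 FPKM, chemokines at 5 FPKM, and ketogenesis after centring by gene length.

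**Figure D2:**
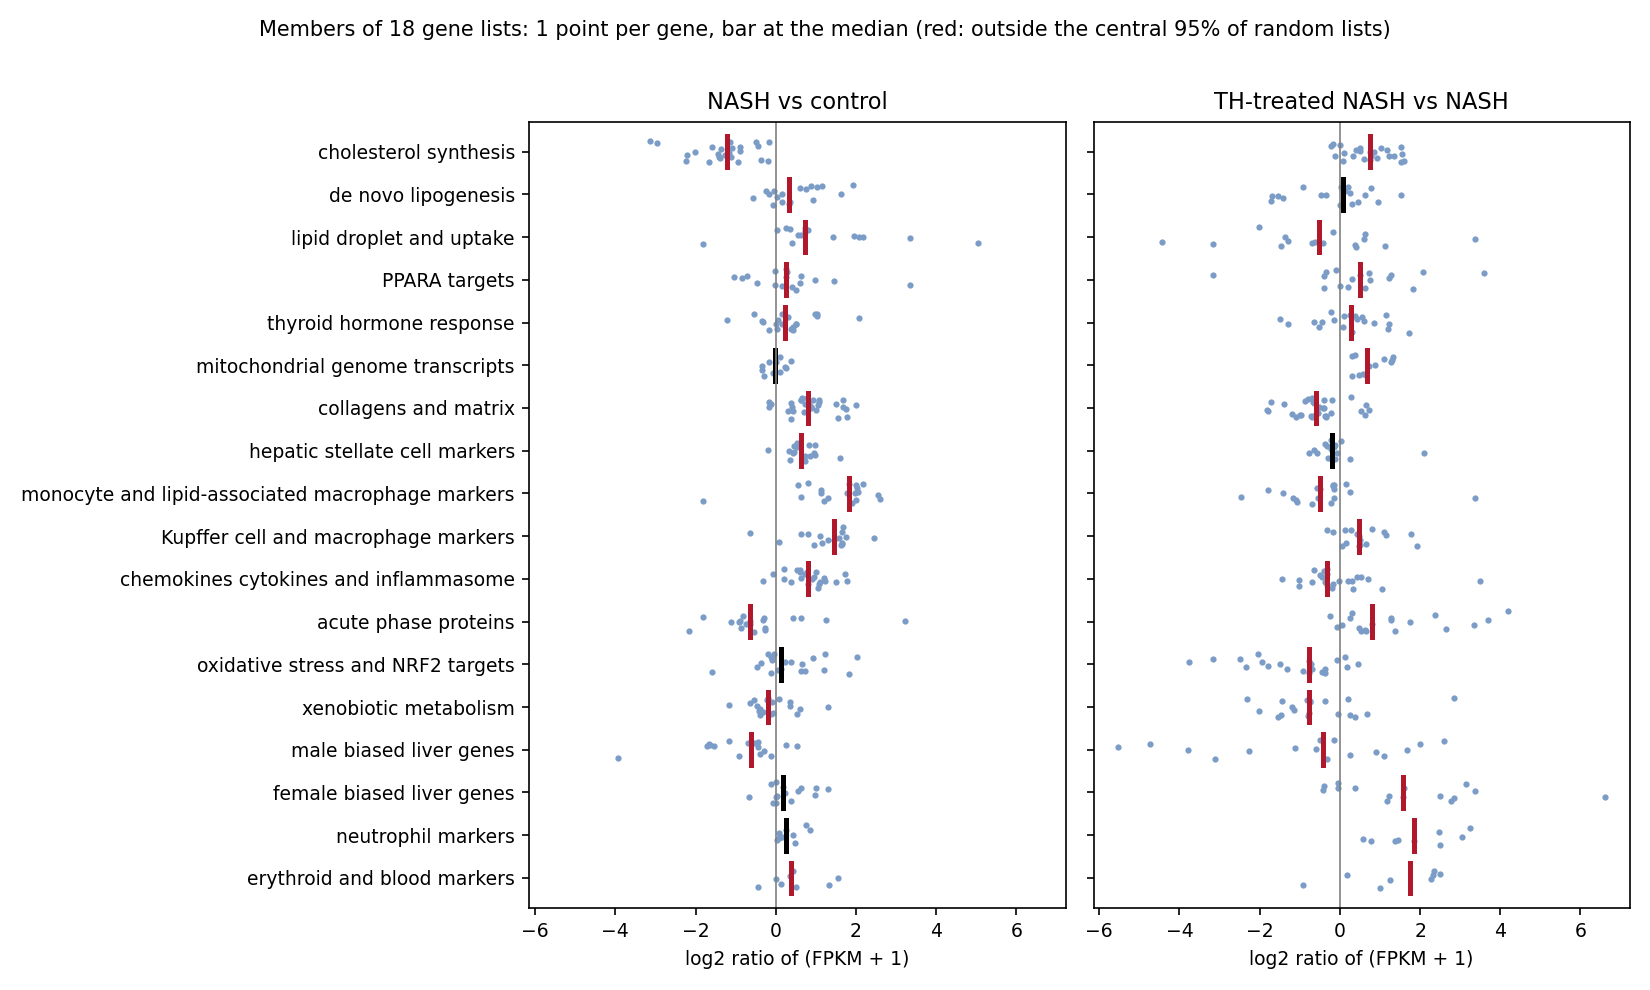
Log2 ratio of (FPKM + 1) for the members of 18 gene lists in NASH vs control and in TH-treated NASH vs NASH, 1 point per gene, with a bar at each list's median that is red where it lies outside the central 95% of random lists. Cholesterol synthesis has medians of −1.21 and 0.76, collagens and matrix 0.81 and −0.59, and neutrophil markers 0.26 and 1.85.

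Both comparisons share the NASH library. Of the 383 genes higher in NASH, 84 (21.9%) were at least 2-fold lower again in TH-treated NASH, where independent lists would share 10.9, and 12 were 2-fold higher still, where independent lists would share 8.64. Of 83 genes lower in NASH and measured in both comparisons, 40 (48.2%) were at least 2-fold higher again against 1.87 for independent lists, and 8 were lower still against 2.37. The genes that were off and back by the most in both steps were Cidea, Cfd, Cidec, Gpnmb, Ubd, Gpc1, Sulf2 and Gstm3, higher in NASH, and Enho, Serpina1e, Moxd1 and Saa2, lower in NASH. Sulf2, which edits heparan sulfate, stood at 1.18, 8.74 and 1.27 FPKM and the glypican gene Gpc1 at 3.11, 17.4 and 2.52 FPKM in control, NASH and TH-treated NASH, while Moxd1 stood at 18.9, 0.441 and 7.25 FPKM. Against control, 200 of the 383 higher genes were still at least 2-fold off in TH-treated NASH and 103 lay within 1.5-fold, and of the 83 lower genes 29 were still off and 23 lay within 1.5-fold. Over the 11835 genes at 1 FPKM or more in at least 1 library, the log2 ratios of both comparisons correlated at −0.27. Draws of 3 simulated unchanged libraries gave −0.49 on average from counting noise in the shared library alone. The covariance was −0.0656 against −0.00309 simulated, a difference of −0.0625. Part of these overlaps may come from the shared NASH library, which cannot be split.

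**Figure D3:**
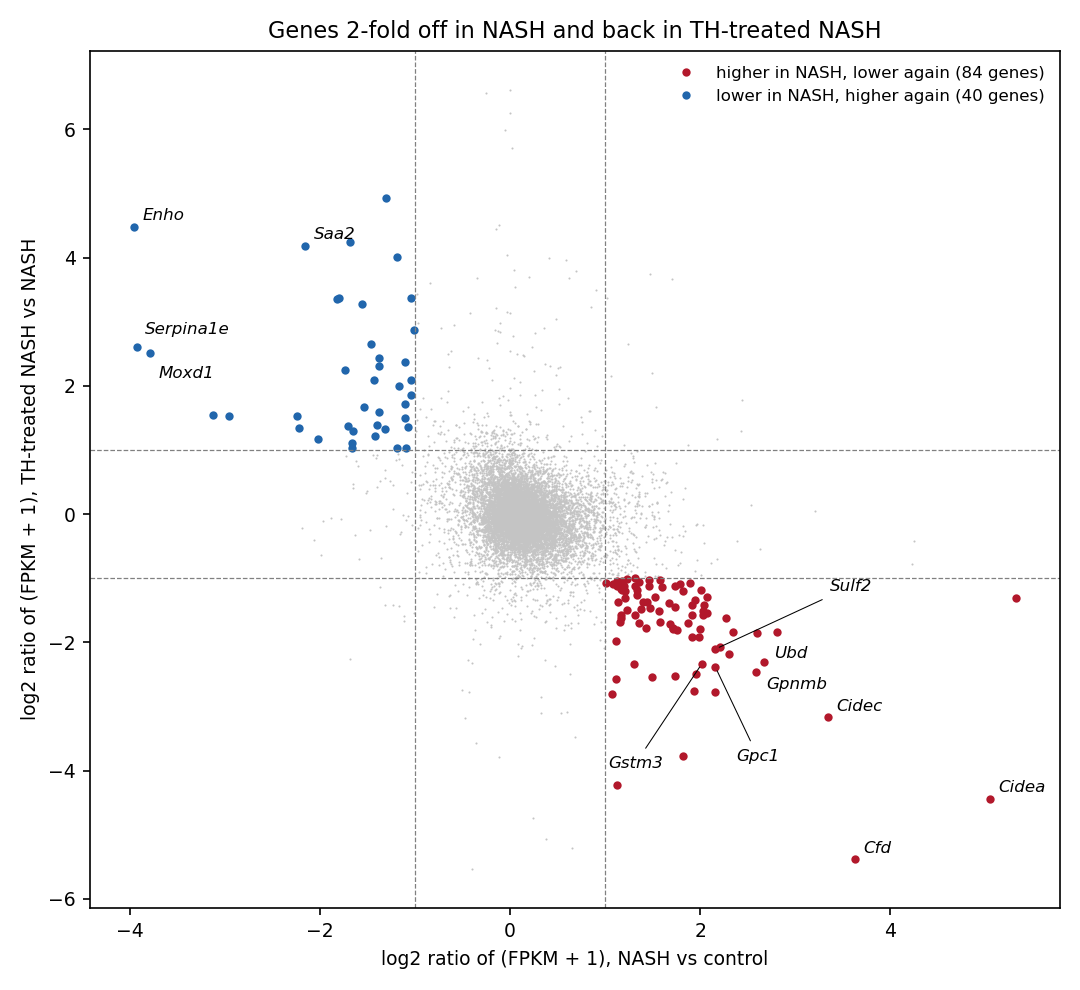
Log2 ratio of (FPKM + 1) of each gene in NASH vs control (horizontal) and in TH-treated NASH vs NASH (vertical), with dashed lines at 2-fold. Red points are the 84 genes higher in NASH and lower again, blue points the 40 genes lower in NASH and higher again, and the 12 named genes are labelled.

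TH-treated NASH was also set against control, to place the treated liver beside the untreated one on chow. Of 11474 genes, 639 were at least 2-fold higher and 278 lower (69.7% higher), and the split was 445 and 396 (52.9% higher) after TMM scaling, 434 and 411 (51.4% higher) after centring by gene length and 495 and 367 (57.4% higher) without the 50 most abundant genes. The median of all genes was 0.12 as deposited and −0.05 after TMM scaling. Col1a1 stood at 1.23 against 1.31 FPKM, 1.06-fold lower with a counting interval (0.913 to 1.24) that includes 1. Collagen and matrix genes had 8 of 32 higher and 1 lower with a median of 0.23 (percentile 87.1). Stellate cell markers had 8 of 16 higher and none lower with a median of 0.52 (percentile 99.87). Kupffer cell and macrophage markers had 16 of 17 higher with a median of 1.71 (percentile 100), with Marco 23.99-fold higher (21.5 to 26.8), and lipid-associated macrophage markers 15 of 19 higher with a median of 0.81 (percentile 100). Lipid droplet and uptake genes had 10 of 16 higher and 2 lower with a median of 0.72 (percentile 100), and cholesterol synthesis 13 of 24 lower with a median of −0.67 (percentile 0). Male-biased genes had a median of −1.36 (percentile 0) and female-biased genes of 1.60 (percentile 100), beside neutrophil markers at 2.12 (percentile 100). The female-biased and neutrophil lists hold members that entered only through TH-treated NASH, which lifts their medians. Over the 3 comparisons, 76 of 117 list medians lay outside the central 95% of random lists, where 5.85 would for random lists. Some lists share members and the 3 comparisons share libraries, so the 117 medians are not separate results.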

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

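Thinning to equal depth, centring by gene length, the counting-interval requirement and leaving out blood, Mup and sex-biased genes were chosen after seeing the data; all other settings were planned. No paired analysis was possible because each group has 1 library, and for the same reason leaving out libraries in turn and limma were not run.

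Of the counts of genes under the alternatives, 103 stayed within 1.5 times and 47 moved further. With a pseudocount of 0.1 FPKM the genes higher and lower numbered 872 and 153 in NASH vs control, 538 and 611 in TH-treated NASH vs NASH, and 1145 and 454 in TH-treated NASH vs control; 185 genes were higher in NASH and lower again, 62 lower and higher again, and 31 higher still. With 5 FPKM the numbers were 101 and 54, 168 and 149, 227 and 125, then 34, 22 and 6, with 5 lower still. A pseudocount weighs on low genes by construction. Among genes of at least 5 FPKM, 228 were higher in NASH vs control and 51 were higher and lower again, from fewer genes. Scaled to equal totals, which raises FPKM against the fixed pseudocount and also shifts TH-treated NASH against NASH (median of all genes −0.14), 653 were higher in NASH vs control, 577 lower in TH-treated NASH vs NASH and 444 lower against control, 147 were higher and lower again and 19 higher still; how much each of these adds was not tested. TMM scaling multiplied NASH values by 0.868 and control values by 1, which lowers the ratios of NASH to control. With it 137 genes were lower in NASH vs control, and the median of all genes was −0.05. A 1.5-fold threshold gave 1208 and 296, 996 and 1060, 1817 and 801, with 288 and 121 back and 82 and 32 further. A 4-fold threshold gave 36 and 11, 81 and 48, 107 and 41, with 11 and 4 back and 0 and 0 further. No count moved by more than 1.5 times when thinned, centred by gene length, required to pass 2-fold by the counting interval (365 and 85, 292 and 302, 594 and 252), taken without blood, Mup and sex-biased genes (366 and 77, 267 and 308, 581 and 264), scaled by median of ratios, rescaled without the 50 most abundant genes, taken over protein-coding genes or unfiltered; FPKM is already scaled by depth, so thinning only adds counting noise.

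Of the list medians under the alternatives, 1192 kept direction and call, 23 lost their call and 20 gained one. Another 47 medians without a call turned sign or reached 0, and 2 with a call turned sign. The list for adipose, pancreas and gut in NASH vs control turned to −0.00407 with no filter on low values, and mitochondrial biogenesis and uncoupling in NASH vs control turned to 0.14 among genes of at least 5 FPKM; both settings change which members are measured. Without expression matching, 109 of 117 percentiles kept their call, 4 lost it and 4 gained one. Those gained were nuclear oxidative phosphorylation in NASH vs control (57.8 to 1.1) and in TH-treated NASH vs NASH (65.4 to 99.6), hepatocyte markers in TH-treated NASH vs NASH (84.7 to 99.9) and the unfolded protein response in TH-treated NASH vs control (3.28 to 2.46). Of the log2 ratios of named genes, 4107 stayed within their counting interval and 2157 moved beyond it. Depth limits low genes: a median of 180, 156 and 133 fragments lay behind a gene near 1 FPKM.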

Other observations

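The tests of explanations for the 3 patterns at the end of this part, thinning and centring by gene length were chosen after the results were seen; the gene lists, their placement among random lists and the other settings named here were fixed before. Interferon response genes were higher in NASH than in control in 17 of 22 cases with none lower, with a median log2 ratio of 0.92 (percentile 100). In TH-treated NASH against NASH 8 of 22 were higher and none lower, with a median of 0.29 (percentile 99.9). Ifi27l2a, an interferon-induced gene, stood at 9.30, 36.7 and 78.4 FPKM in control, NASH and TH-treated NASH, and the guanylate binding proteins Gbp3 at 1.73, 5.27 and 12.3 and Gbp2 at 1.06, 4.03 and 3.07. B and plasma cell markers had 4 of 7 higher in NASH (median 0.70, percentile 99.9) and 3 of 7 higher in TH-treated NASH than in NASH (median 0.53, percentile 99.7), where the immunoglobulin heavy chain gene Ighm was 6.38-fold higher than in NASH; both calls were lost among protein-coding genes, which leave out the immunoglobulin segments. T and NK cell markers had 1 of 5 higher and none lower in NASH (median 0.34, percentile 66.1). In TH-treated NASH against NASH 2 of 5 were higher (median 0.31, percentile 91.6), with Gzmb at 0.284, 0.570 and 1.44 FPKM. Gzmb, Gzma and Cd3g entered the list only through TH-treated NASH. As ratios of FPKM on few fragments, Nkg7 was 3.12-fold (2.02 to 4.96) and Gzma 2.55-fold higher (1.16 to 6.04) in NASH than in control. Gzmb was 2.01-fold (1.16 to 3.56) and Cd3g 1.72-fold higher (0.982 to 3.05). Liver endothelial markers had 1 of 14 higher in NASH (median 0.25, percentile 93.0), Vwf at 3.22-fold (2.67 to 3.89), and none off in TH-treated NASH against NASH, with a median of −0.01 (percentile 59.7) that was positive under median-of-ratios scaling and centring by gene length.

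Cell cycle genes had 8 of 13 higher in NASH (median 0.67, percentile 99.98), among them the inhibitor Cdkn1a, 17.4-fold higher (12.5 to 24.8), and Ccnd1, cyclin D1, 2.94-fold higher; in TH-treated NASH against NASH 3 of 13 were higher with a median of −0.03 (percentile 60.8), positive after centring by gene length and among genes of at least 5 FPKM, and Cdkn1a was 2.70-fold higher. The unfolded protein and integrated stress response had 4 of 20 lower and 1 higher in NASH (median −0.14, percentile 0.11) and 3 higher and 2 lower in TH-treated NASH against NASH (median −0.07, percentile 25.9). Asns, asparagine synthetase, was 5.36-fold lower (4.37 to 6.61) and then 7.99-fold higher (6.53 to 9.86). Clock genes had 1 of 17 lower in NASH, Nfil3 at 1.75-fold (median −0.05, percentile 1.12, a call lost with no filter), and 4 lower and 1 higher in TH-treated NASH against NASH (median −0.18, percentile 7.35), with Nr1d1 1.95-fold lower; the hour of tissue collection is not given in the sources used here. Immediate early and handling genes had 3 of 14 higher and 2 lower in NASH (median 0.07, percentile 25.02, negative under median-of-ratios scaling, TMM scaling, centring by gene length and at 5 FPKM or more) and 5 higher and 1 lower in TH-treated NASH against NASH (median 0.21, percentile 98.6, a call lost when thinned), with Egr1 10.7-fold higher (9.77 to 11.7). The list for adipose, pancreas and gut tissue had 4 members at 1 FPKM or more. Its median was 0.78 (percentile 99.6) in NASH against control, a call lost with a pseudocount of 0.1 FPKM. In TH-treated NASH against NASH the median was −0.30 (percentile 12.4), positive with that pseudocount. In NASH against control 2 members were higher, Cfd, named above, and Fabp2 at 3.81-fold, and 1 was lower, the elastase gene Cela1. Cela1 stood at 17.5, 10.8 and 56.9 FPKM. No mesothelial or gallbladder marker reached 1 FPKM, the highest being 0.844.

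The median of the male-biased list was lower and that of the female-biased list higher in TH-treated NASH than in NASH. The male-biased list was mixed, with 7 of 16 members lower and 5 higher. RNA of female mice in place of male would lower Y-linked genes with Cyp4a12a, but their summed fragment ratio was 1.03 (0.997 to 1.07), below 1 only after scaling to equal totals with factors of 1.90 and 1.76 or without the 50 most abundant genes, and Xist held 11, 6 and 5 fragments in control, NASH and TH-treated NASH. Reads moving between Cyp4a12a and Cyp4a12b would keep their sum, which was 83.8-fold lower, and reads of other Cyp3a genes counted for Cyp3a44 and its 3 close copies would rise no more than those genes, at most 2.66-fold (0.943 to 8.53, Cyp3a57), against a counting interval from 2540 upward for the sum of the 4 on 1 NASH fragment. Reads moving among close Mup copies may account for part of the spread among Mup9, Mup18, Mup20 and Mup21. The sum over the family was 1.15 times that of NASH. Opposite changes of single members can also leave such a sum, so it cannot decide. How alike these genes are in sequence was not examined. An effect of thyroid hormone on sex-biased transcription stays open, as the 1 library cannot test it.

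Neutrophil markers and haemoglobin were higher in TH-treated NASH than in NASH. If all haemoglobin RNA came from blood, more blood of unchanged make-up would leave neutrophil genes at or below the haemoglobin ratio of 4.99 (4.89 to 5.09). But 6 of 13 neutrophil genes had intervals wholly above it, among them Mpo at 23.3 (12.4 to 49.4) and Ltf at 34.7 (16.5 to 87.5), while 4 lay wholly below it, such as Csf3r at 1.73. Haemoglobin RNA of other origin in NASH would lower that ratio and was not tested, so these values do not exclude more blood. A lower share of hepatocytes would raise other cell types alike, but the endothelial median was −0.00923, with quartiles of −0.09 and 0.10, against neutrophil quartiles of 1.38 and 2.497. Some neutrophil members entered only through TH-treated NASH, which raises the neutrophil quartiles. Blood of another make-up, immature neutrophils in the liver and an effect of the hormone may each add to it and were not tested. Alas2, a gene of erythroid cells, went the other way at 44.3 and 22.8 FPKM. Prtn3, an early neutrophil granule protease, stood at 1.04 and 61.2 FPKM, but Elane of the neutrophil list only at 0.740 and 1.99 FPKM.

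In all, 124 genes were 2-fold off in NASH and 2-fold back in TH-treated NASH. Counting noise of the shared library would give as many without any difference, but 100 draws of 3 unchanged libraries at these depths gave at most 4. That the single NASH library deviates from other livers of its group may account for part of the pattern, because such a deviation brings a negative covariance (observed minus simulated −0.0625) with or without an effect of the hormone, and 1 library cannot separate them. An effect of thyroid hormone on these genes stays open beside it.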
